A study of Homo sapiens with 4 samples.

How the data were processed

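Messenger RNA was measured in HOP-62 cells, an established human lung adenocarcinoma line, with 4 Illumina expression BeadChip arrays. Per the labels' protocols, cells either took up a synthetic microRNA mimic transiently (a negative control mimic or a mimic of miR-10a*, the older name of the strand now called hsa-miR-10a-3p) or were transfected with a plasmid (an empty Flag vector or one carrying the coding sequence of HDAC5, a class IIa histone deacetylase). Total RNA was extracted with Trizol and cleaned on columns with DNase, and biotin-labelled cRNA was hybridised, per the labels' protocols. Each group held 1 array. Groups were taken from the sample titles. For the fourth array the title names HDAC5 and the description names only the vector, and the title was followed.

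The deposited signal table gives for 47224 probes an intensity per array on a linear scale, not normalized per the file headers, and a detection p-value per probe and array, which the authors deposited beside each signal. The scanner software is not given in the sources used here. The lowest signals lay between 67.2 and 96.2 on the 4 arrays, so no background had been subtracted. The deposited processed table holds linear intensities whose 4 columns share nearly the same set of values, with medians between 119.8 and 119.9. Its values were those of the signals after quantile normalization without background correction, with no log, no centring and no direction to settle. Its rows needed re-keying before use: 10571 of 47224 rows (22.4%) held the values of their own identifier, and after the identifiers had been moved by up to 7 rows, 47217 rows matched the ranks of the signals on all 4 arrays within 0.02 on the log2 scale. That match was made sample by sample, so it also tied each signal column to its sample. In the signal table the empty vector array carries another name, a mock control, and was assigned by that name.

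Signals were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3: normexp with the background inferred from the detection p-values, an offset of 16, and quantile normalization over the 4 arrays, followed by log2. Differences are differences of these log2 values between 2 arrays. Because of the offset, differences of dim probes are smaller than the true ones. Names came from an annotation of the platform. Of the 47224 probes, 30106 had 1 gene symbol, 8 had several and 17110 were not listed and stay unnamed here. Of the named probes, 30067 had a gene identifier found in the GRCh38.p14 gene table used for names, and 0 symbols changed. The 20041 named genes were each represented by the probe with the highest mean over the 4 arrays, and 6689 genes had more than 1 probe. No genome sequence or 3' UTR was used here, so the comparison of genes with and without seed sites for miR-10a* was not run, and no coordinates are given.

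A gene was measured in a comparison when its probe had a detection p-value under 0.01 on at least 1 of the 2 arrays. It was counted higher or lower when the 2 arrays differed by at least 1.5-fold. With 1 array per group there is no replicate check on any difference, no test was made across genes, and no p-value or standard error is given for a comparison. Where the dimmer array did not detect the probe, the fold is given as a bound ("at least"), taken against the lowest normalized value among that array's detected probes or the probe's own value if that was higher. Those lowest values lay between 5.33 and 5.70 on the log2 scale.

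Named genes were set by a rule written before the data were examined: HDAC5; the 12 highest and 12 lowest differences of each comparison among measured genes with an official-looking symbol; from each of 32 gene lists up to 4 counted members with the largest differences; and up to 5 genes for each combination of directions over both comparisons. The lists were fixed at the same time. The result of 1 of them is not reported here. A list's median difference is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these arrays. Lists also reached extreme percentiles between the control arrays, so an extreme percentile alone does not point to a treatment. There interferon-stimulated, antigen presentation, NF-kB and cholesterol and fatty acid synthesis genes lay at 0 and hypoxia and glycolysis genes at 100. Ribosomal proteins lay at 36.3 and oxidative phosphorylation genes at 52.4. Lists with fewer than 5 measured members got no percentile.

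Precision was judged in 3 ways. Signal over background, the median signal of the 12843 probes detected on all 4 arrays over the median background, was 4.29 on the control mimic array, 3.02 on the miR-10a* array, 3.36 on the empty vector array and 3.49 on the array labelled HDAC5. The number of arrays, 1 per group, limits the precision. Pairs of probes of the same gene gave a standard deviation per probe of 0.30 on the log2 scale for the mimic comparison and 0.24 for the HDAC5 comparison. The procedure was also tested on simulated data with 200 changed genes per comparison and with brightness, background and probe noise estimated from the arrays. The probe noise was taken from normalized values, which already hold background noise, and background noise was then added. The simulated noise therefore need not equal the real noise. In the simulated mimic comparison, run on 12366 genes, 34.3% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 96.9% of those changed 4-fold were counted, and 11.8% of unchanged genes were counted too. In the simulated HDAC5 comparison, run on 12133 genes, these shares were 38.8%, 85.1% and 100%, with 7.01% of unchanged genes counted. More genes were measured in the simulated arrays than in the real ones (10333 and 10094). Variation that the probes of a gene share, as between cultures or transfections, was not simulated. These shares therefore cover probe and background noise as simulated only, and not how often unchanged genes are counted in the real comparisons.

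Alternatives fixed before the data were examined were median scaling, no background correction, an offset of 50, the re-keyed processed table, normalization of the 2 arrays alone, detection limits of 0.05 or on both arrays or none, a 2-fold size rule, and the mean of a gene's detected probes. Except for that mean, each alternative kept the probe chosen above. Added after the data had been seen were the other control array as reference and a restriction to genes detected on all 4 arrays. A gene or list was taken as moved when it shifted by more than 0.27 on the log2 scale, the mean of both standard deviations per probe, and a correlation when it shifted by more than 0.1. These tolerances were set after a first look at the values. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.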

Results

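Gene expression was profiled in HOP-62 lung adenocarcinoma cells on 4 BeadChip arrays, with 1 array in each group: a control mimic, a miR-10a* mimic, an empty vector, and a vector for HDAC5, an enzyme that removes acetyl groups from histones and other proteins. The design gives 2 comparisons, the miR-10a* mimic minus the control mimic and the HDAC5 vector minus the empty vector, and both differences can be set against each other because they share no array. The median probe signal was 141 on the control mimic array, 102 on the miR-10a* array, 109 on the empty vector array and 114 on the array labelled HDAC5. Those arrays detected 16204, 14108, 15064 and 15454 of 47224 probes. As there are no replicates, every difference below is one between single arrays, and the difference between both control arrays serves as a scale for it.

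HDAC5 itself was not detected on any of the 4 arrays. Probe ILMN_1810856 had a detection p-value of 0.261 on the array labelled HDAC5 and 0.468 on the empty vector array, and probe ILMN_2388166 had 0.114 and 0.0883. Whether these probes lie within the transfected coding sequence is not known here, so they neither bear out the label nor go against it. The array is called "the array labelled HDAC5" throughout, and each direction drawn from it rests on its title.

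The question of the first comparison was which transcripts differ when miR-10a* is supplied. Among immediate early transcription factors, FOSB was 20.1-fold lower on the miR-10a* array than on the control mimic array, FOS 15.6-fold lower and EGR1 5.74-fold lower. Against the empty vector array they were 1.59-fold, 3.51-fold and 3.18-fold lower. FOSL1 and FOSL2 went the other way, 1.86-fold and 1.74-fold higher than on the control mimic array. Of 27 interferon-stimulated genes, the antiviral effectors that cells switch on after interferon signalling, 15 were also lower, with OASL at least 5.63-fold lower, IFITM1 at least 5.65-fold lower and IFIT1 2.55-fold lower. Against the empty vector array OASL was at least 1.08-fold, IFITM1 at least 2.87-fold and IFIT1 2.08-fold lower. Among the highest transcripts were those for GREM1, a secreted BMP antagonist, at 2.59 on the log2 scale, TAGLN, an actin-binding protein of contractile cells, at 2.51, and HMOX1, the heme-degrading oxygenase, also at 2.51. The inflammatory cytokine IL1A was 4.68-fold higher and the cytokine IL24 at least 2.56-fold higher.

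Of 10333 genes measured in this comparison, 1307 were higher and 1469 lower by at least 1.5-fold, and 296 and 480 by at least 2-fold. The control arrays differed from each other by at least 1.5-fold in 17.7% of their measured genes, against 26.9% here, and they differ in the kind of transfection as well. Scaling by array medians put the median of all measured genes at 0.10 on the log2 scale in place of 0.01 and turned the split to 1621 higher and 976 lower, so the balance of directions is not settled. Against the empty vector array, 829 of the genes counted higher and 825 of those counted lower were counted the same way. Of the 106 named genes counted here, 73 were counted the same way against that array and 53 moved by more than 1.5-fold.

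The remaining genes at the low end were LXN, a carboxypeptidase inhibitor, at −3.50 on the log2 scale, the zinc transporter SLC39A10 at −3.31, BEX1 at −3.21 (a second probe read −0.64), RARRES1, a retinoid-responsive gene, at −3.00, complement factor CFB at −2.82 and TNFSF10, the death ligand TRAIL, at −2.70. The extracellular sulfatase SULF1 was at least 7.4-fold lower, the sodium channel subunit SCNN1A at least 5.08-fold lower and the prostaglandin synthase PTGDS at least 2.82-fold lower. SULF1 was detected on the control mimic array and on none of the other arrays. Against the empty vector array RARRES1 was at −0.83, TNFSF10 at −1.77, SLC39A10 at −1.91, LXN at −1.98 and BEX1 at −2.34, and PTGDS, undetected on the miR-10a* array, gave no bound above 1-fold. At the high end stood the non-coding RNA SNAR-A1 at 2.42, the acyltransferase GPAT3 at 1.89 and the non-coding RNA MANCR at 1.87, with MANCR at −0.20 and SNAR-A1 at 0.53 against the empty vector array. ACTG2, a smooth muscle actin, was at least 2.67-fold higher, the calcium-binding protein CALB2 at least 3.06-fold, TRIML2 at least 3.62-fold and the NADPH oxidase NOX4 at least 2.88-fold. A second CALB2 probe went the other way, at −0.64.

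Of 27 interferon-stimulated genes measured, 15 were lower and 0 higher, with a median of −0.72 that lay at percentile 0 of the random lists. With undetected sides at their floor the median was −0.65. The list's median for the empty vector array minus the control mimic array also lay at percentile 0. Against the empty vector array the same list had a median of −0.08. IFIT2 went from −1.68 to −0.28 with that change of control, OASL was at least 1.08-fold lower, IFI27 turned to at least 3.37-fold higher and IFI44 to 0.45. Of 18 immediate early genes, 6 were lower and 3 higher, with a median of −0.16. FOSB was at −0.66 and FOS at −1.81 against the empty vector array, less than their −4.33 and −3.96 against the control mimic. Antigen presentation genes, which load and display peptides on the cell surface, had 5 lower and 1 higher of 13 and a median of −0.42 at percentile 0.11. CD74 was at −1.25, HLA-C at −1.05 and HLA-DMA at −0.84, while the list's median was 0.35 against the empty vector array, HLA-C turned to 0.14 and CD74 was at −0.16. Cholesterol and fatty acid synthesis genes had 7 lower and 0 higher of 17 and a median of −0.42 at percentile 0.1, including the regulator SREBF1 at −1.24, INSIG1 at −1.13 and the desaturase SCD at −0.88. That median also turned, to 0.16, against the empty vector array, where SREBF1 was at −0.08.

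Genes of DNA replication and the G1/S transition had a median of 0.51 at percentile 100, with 5 of 23 higher and 1 lower. CCNE1, the cyclin of S phase entry, was 2.43-fold higher and the flap endonuclease FEN1 2.26-fold higher, while the thymidylate synthase TYMS was 2.30-fold lower. Against the empty vector array the list had 4 higher and 5 lower of 23 and a median of 0.21. Mitotic genes had 1 higher and 2 lower of 25, with the mitotic kinase CDK1 at −0.91 and the spindle protein TPX2 at −0.75. Proteins of the microRNA pathway had 5 higher and 0 lower of 12 and a median of 0.36 at percentile 97. TARBP2, a Dicer partner, was at 1.57, the Drosha partner DGCR8 at 1.12, AGO2, which holds the guide strand, at 0.96, and GEMIN4 at 0.95. A second TARBP2 probe read 0.20. Tubulins and microtubule proteins had 3 higher and 1 lower of 21 and a median of 0.30 at percentile 99.1, with TUBB2A at 1.62, TUBA4A at 1.22 and MAP4 at 1.18, and a median of 0.04 against the empty vector array. Among the deacetylases, 3 of 14 were lower and 1 higher, with HDAC9 at least 1.36-fold lower, HDAC4 2.30-fold lower and SIRT7 1.78-fold higher, and the median was −0.25.

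Hypoxia and glycolysis genes had 7 lower and 1 higher of 20, a median of −0.24 at percentile 0.51, and the glucose transporter SLC2A3 at −1.38. That list depends on the control, as it was high on the empty vector array, at a median of 1.01 above the control mimic array. Against the empty vector array SLC2A3 was at −2.02, and DDIT4 went from −0.77 to −2.16. Wnt and Notch pathway genes had 5 lower and 1 higher of 17 and a median of −0.25 at percentile 1.96, with NOTCH3 at −1.92 and FZD1 at 1.02. Fibroblast and endothelial markers, included for cells other than the cancer line, had 4 lower and 0 higher of 6 and a median of −0.62 at percentile 0.79. Their member LUM was at −0.97, and at 0.03 against the empty vector array. COL6A3 and PDGFRB of that list read 11.88 and 11.25 on the control mimic array, where the reference genes had a median of 11.85. The list's values therefore need not come from other cells. Genes of the integrated stress and unfolded protein responses had 7 higher and 1 lower of 18 with a median of 0.21, among them ASNS, the asparagine synthetase, at 0.76 and the phosphatase subunit PPP1R15A at 0.82. In the p53 target list 3 of 14 were lower and 1 higher, with a median of −0.29, BBC3 at least 1.49-fold lower and CCNG1 2.003-fold lower, but the median was 0.13 against the empty vector array.

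Lists that showed few or mixed differences in this comparison were the MEF2 and class IIa deacetylase targets with 4 higher and 3 lower of 13, apoptosis regulators with 1 and 3 of 12, autophagy and lysosome genes with 2 and 1 of 17, and NF-kB targets with 4 and 7 of 22. Mesenchymal markers had 4 higher and 2 lower of 16, with COL1A1 at 1.36. Epithelial junction and keratin genes had 0 and 3 of 10, with KRT19 at −1.42 but at 0.71 against the empty vector array. Matrix, protease and integrin genes had 5 and 4 of 20, TGF-beta and BMP pathway genes 1 and 2 of 16, replication-dependent histones 3 and 0 of 9 (0 and 2 of 10 against the empty vector array), heat shock proteins 1 and 1 of 14, NRF2 targets 2 and 2 of 14, and HOX genes 0 and 2 of 12. Of the lung lineage markers, 3 were measured, with 0 higher and 1 lower, GATA6, which was close to its detection limit. Of the blood and immune markers, CD14 was at −1.20 and CD68 at 0.67, with −0.16 for a second CD68 probe. Ribosomal proteins had 0 of 18 counted either way and a median of −0.07, oxidative phosphorylation genes 1 higher and 0 lower of 18 and a median of 0.02, and reference genes 0 higher and 1 lower of 13 and a median of −0.11. The ribosomal and reference medians were above 0 when arrays were scaled by their medians, with the ribosomal one at 0.17.

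Pairs of probes gauge the probe noise in these values. They share the RNA and transfection of their arrays, so they do not measure how far a difference would repeat. Across 1916 genes with a pair of probes detected on both arrays, the probes' differences correlated at r = 0.578 in the mimic comparison. For 293 of 347 genes counted by the brighter probe, the other probe had the same direction (84.4%). In the HDAC5 comparison the correlation was 0.768 across 2082 genes and the direction was shared by 361 of 384 (94.0%). For the control arrays against each other the correlation was 0.526 across 2141 genes, and the direction was shared by 224 of 284 (78.9%). These are correlations across genes within arrays, and genes are not independent replicates.

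**Figure D1:**
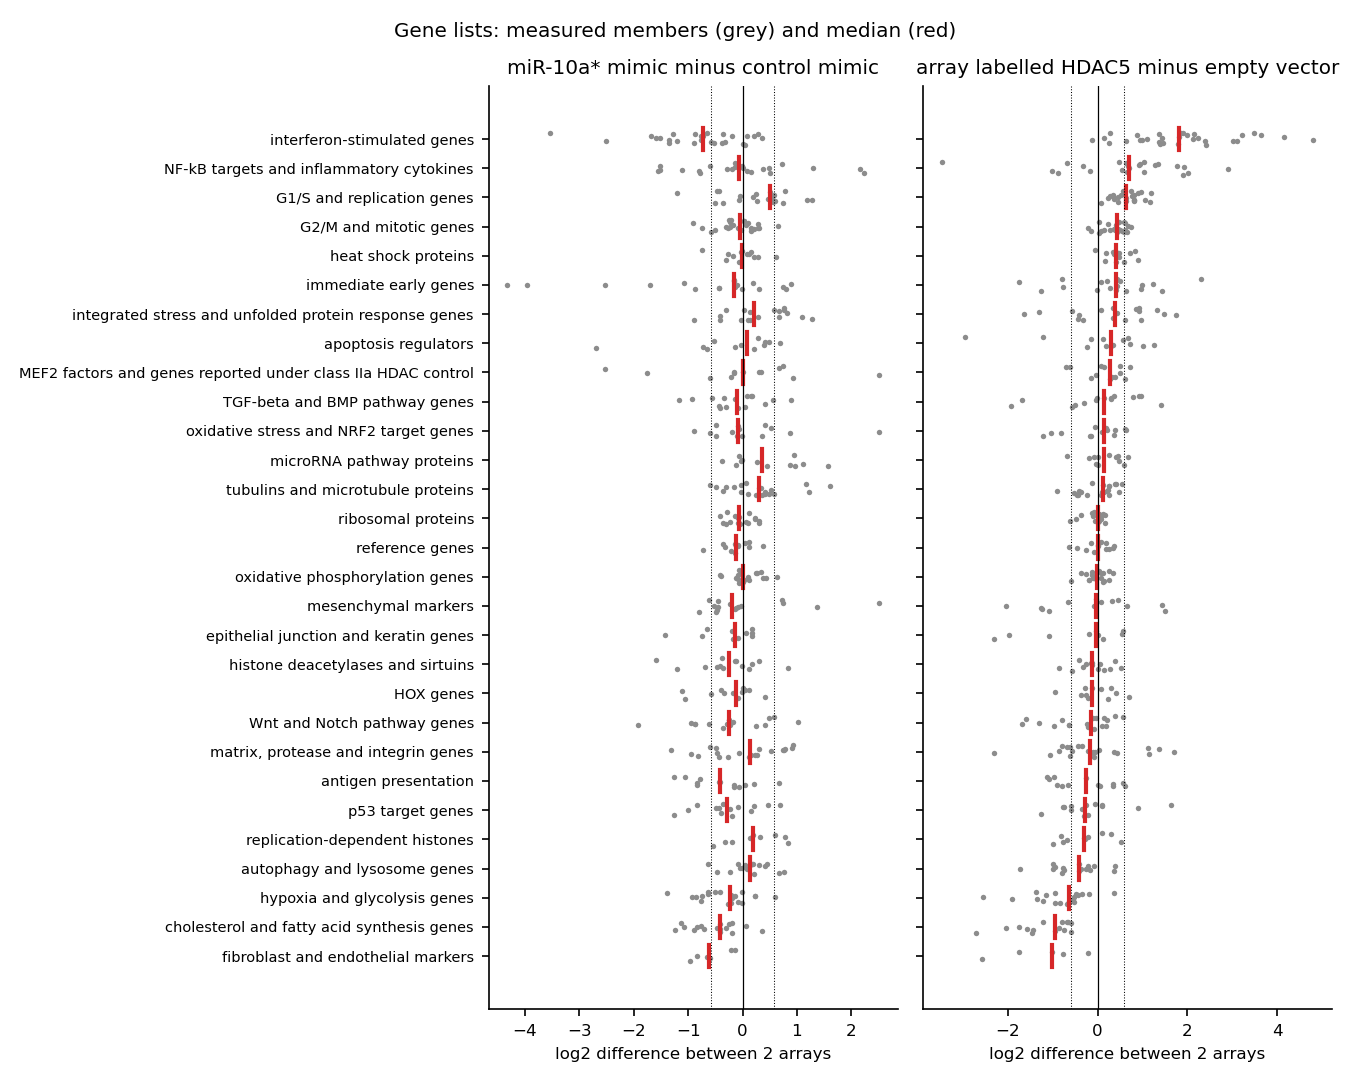
Log2 differences of the measured members of the gene lists shown (grey points) and their median (red bar), for the miR-10a* mimic minus the control mimic on the left and the array labelled HDAC5 minus the empty vector on the right; dotted lines mark a 1.5-fold difference. The interferon list stands at a median of −0.72 on the left and 1.80 on the right, and the cholesterol list at −0.42 and −0.95.

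The second comparison asked which transcripts differ when HDAC5 is expressed from a vector. Among the highest transcripts on the array labelled HDAC5 were interferon-stimulated genes. IFI27 was at least 15.8-fold higher than on the empty vector array, MX1, an antiviral GTPase, 11.2-fold higher and IFIT1 9.28-fold higher. OAS2, an RNA-activated antiviral synthetase, was at least 12.6-fold higher by its brightest probe. Its 3 other measured probes read 0.99 to 3.06 on the log2 scale. Low on that array were PCDH20, a protocadherin, at least 11.9-fold lower, IGFBP5, a binding protein of insulin-like growth factors, 11.5-fold lower, and PTGS2, the inducible cyclooxygenase, 11.2-fold lower. Of 15 lipid synthesis genes 14 were lower, with the desaturase SCD 6.55-fold lower and INSIG1 4.15-fold lower. Of 24 G1/S and replication genes 13 were higher, with the licensing factor CDT1 2.26-fold higher.

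Of 10094 genes measured, 1107 were higher and 1375 lower by at least 1.5-fold, which is 24.6% against 17.7% between the control arrays, and 265 and 494 differed by at least 2-fold. Against the control mimic array in place of the empty vector, 743 of the genes counted higher and 962 of those counted lower were counted the same way. All 12 named genes at the high end and 11 of the 12 at the low end were among them. Of the 121 named genes counted here, 100 were counted the same way and 64 moved by more than 1.5-fold, with IFI27 at 1.47, OAS2 at 2.45, IFI44 at 1.70, PTGS2 at −2.40 and SEL1L3 at −2.23.

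Further genes at the high end were IFI44L, at least 9.58-fold, OAS3 at 3.11 on the log2 scale, IFI44 at 3.02, IL1A at 2.92, USP18, which removes the ubiquitin-like modifier ISG15, at least 2.95-fold, EPSTI1 at 2.57, KISS1, the precursor of kisspeptin, at 2.53 and IFI6 at 2.42. A second IFI44L probe read 1.53 and a second OAS3 probe 1.76. At the low end were SEL1L3 at −3.47, the phosphodiesterase PDE5A at −3.47, RARRES1 at −3.45, the sulfatase SULF2 at −3.02, TNFSF10 at −2.96, the proteoglycan EPYC at least 4.74-fold lower, COLEC12, a scavenger receptor, at least 5.25-fold lower, and PKD1L1-AS1 at least 5.55-fold lower. EPYC was detected on neither the array labelled HDAC5 nor the control mimic array. ADSS1, an adenylosuccinate synthase, was at least 8.95-fold lower by its brighter probe, but its other probe read 0.27. A second PTGS2 probe read −3.73 and a second IGFBP5 probe −3.10.

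Of 31 interferon-stimulated genes measured, 27 were higher and 0 lower, with a median of 1.80 at percentile 100. Against the control mimic array the median was 1.12 with 24 higher and 2 lower, and OASL turned from 1.98 to −0.40. Antigen presentation genes, which interferons also induce, did not share that direction, with 6 lower and 1 higher of 13 and a median of −0.26. Over the control mimic array their median was −1.08. TAPBP, which loads peptide onto class I molecules, was at −1.14 and HLA-DMA at −1.09. NF-kB targets and inflammatory cytokines had 15 higher and 4 lower of 23 and a median of 0.69 at percentile 100, with IL1B 4.01-fold higher, CXCL2 at 1.77 and IL24 at least 2.84-fold higher, and PTGS2 going the other way. Against the control mimic array that list had a median of 0.0060 with 8 higher and 8 lower.

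Cholesterol and fatty acid synthesis genes had 14 lower and 0 higher of 15 and a median of −0.95 at percentile 0. SREBF1, which encodes a transcription factor of lipid synthesis, was at −1.57 and HMGCS1, an early enzyme of the mevalonate pathway, at −1.76. Against the control mimic array 16 of 17 were lower, with a median of −1.84. Hypoxia and glycolysis genes had 12 lower and 0 higher of 21 and a median of −0.64 at percentile 0, with DDIT4, an inhibitor of mTORC1 signalling, at −2.55, SLC2A3 at −1.90 and ENO2 at −1.37. The list was high on the empty vector array, at a median of 1.01 above the control mimic array, and its median on the array labelled HDAC5 was 0.185 against the control mimic, with P4HA1, PGK1 and ENO2 at 0.02, 0.45 and −0.32. Autophagy and lysosome genes had 7 lower and 0 higher of 17 and a median of −0.41 at percentile 0.11, with GABARAPL1, of the family that coats autophagosomes, at −1.74, the kinase ULK1 2.005-fold lower, the protease CTSD at −0.99 and WIPI1 at −0.95.

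Replication and G1/S genes had 13 higher and 0 lower of 24 and a median of 0.63 at percentile 100, and mitotic genes 7 higher and 0 lower of 25 with a median of 0.42 at percentile 100. The mitotic kinases PLK1 and BUB1 were at 0.74 and 0.68, with PLK1 at 0.53 against the control mimic array. Immediate early genes had 6 higher and 4 lower of 18 and a median of 0.41 at percentile 100, with ATF3 at 2.31 and FOS at −1.76. Over the control mimic array that median was 0.18, with ATF3 at 0.68 and FOS at −3.91. Heat shock proteins had 3 higher and 0 lower of 15 and a median of 0.42 at percentile 99.97, with HSPH1 at 0.89 and HSPA4L at 0.71. Genes of the integrated stress and unfolded protein responses had 8 higher and 2 lower of 18 and a median of 0.39 at percentile 99.9, with ASNS at 1.75, PPP1R15A at 1.33 and VLDLR at least 2.33-fold lower. Apoptosis regulators had 4 higher and 2 lower of 13, with BIRC2 at 1.26, PMAIP1 2.005-fold higher, and CFLAR, an inhibitor of caspase-8, at −1.22. Against the control mimic array PMAIP1 was at −0.0018 and BIRC2 at 0.26, VLDLR was undetected there and on the array labelled HDAC5, and the apoptosis regulators had 1 higher and 2 lower.

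Fibroblast and endothelial markers had 4 lower and 0 higher of 5 and a median of −1.01 at percentile 0.04, with LUM at least 3.36-fold lower and FAP at least 1.88-fold lower. Mesenchymal markers had 3 higher and 5 lower of 13, with COL1A1 at −2.05, SPARC at −1.27, the transcription factor SNAI2 at 1.43 and TAGLN 2.83-fold higher, the last at −0.47 against the control mimic array. Epithelial junction and keratin genes had 0 higher and 3 lower of 9: MUC1 was at least 3.21-fold lower, JUP, a junction plaque protein, at −1.98 and KRT19 at −1.09. Matrix, protease and integrin genes had 4 higher and 7 lower of 22, with LAMB3 at 1.71 and ITGB4 at least 2.57-fold lower. Wnt and Notch pathway genes had 0 higher and 7 lower of 18, with NOTCH3 at −1.69, WNT5A at −1.61 and FZD7 at −1.31, and WNT5A at −0.25 against the control mimic array. TGF-beta and BMP pathway genes had 4 higher and 2 lower of 15, with BAMBI at −1.94, TGFB2 at −1.68 and ID3 at 1.42, the last at −0.31 against the control mimic array. Replication-dependent histones had 0 higher and 4 lower of 10, but none of those 4 was counted lower against the control mimic array, with H2AC18 at −0.16, H2BC5 at −0.58, H2BC21 at 0.29 and H2AC6, undetected on the control mimic array, at least 1.19-fold higher. The p53 targets had 2 higher and 5 lower of 14, with GADD45A at 1.63 and TP53INP1 at −1.26.

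The deacetylases had 0 higher and 1 lower of 14, SIRT4 at least 1.26-fold lower. The MEF2 and class IIa deacetylase targets had 2 higher and 2 lower of 13, with NR4A2 at least 1.30-fold lower. Tubulins and microtubule proteins had 0 higher and 1 lower of 21, NRF2 targets 2 and 3 of 14, microRNA pathway proteins 2 and 1 of 12, and HOX genes 1 and 1 of 11. Of 3 lung lineage markers measured, 0 were higher and 2 lower, FOXA1 at −1.54 and GATA6 at least 1.12-fold. Of the blood and immune markers, CD14 was at −2.31 and CD68 at 0.04. Ribosomal proteins had 0 higher and 1 lower of 18 with a median of 0.01, oxidative phosphorylation genes 0 and 1 of 18 with a median of −0.0049, and reference genes 0 and 1 of 13 with a median of 0.01. The last 2 medians changed sign under some of the other normalizations.

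**Figure D2:**
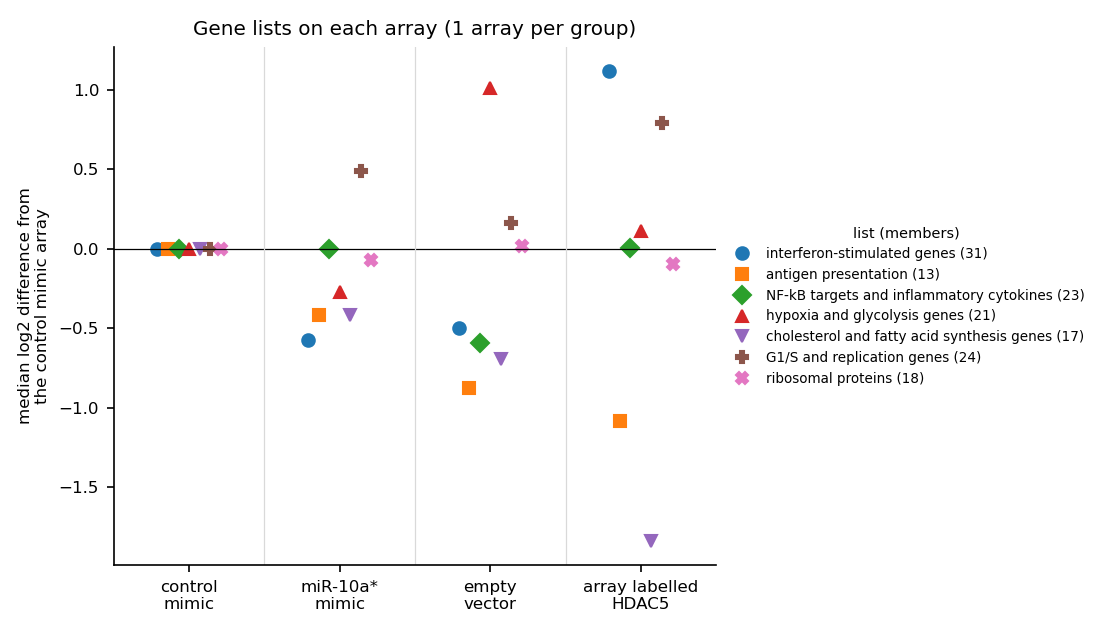
Median log2 difference of the members of 7 gene lists on each array from the control mimic array, which is 0 by construction; 1 array per group, and the number of members is given in the key. Interferon-stimulated genes stand at −0.57 on the miR-10a* array, −0.50 on the empty vector array and 1.12 on the array labelled HDAC5, and hypoxia genes at 1.01 on the empty vector array.

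The third question was whether genes lower with miR-10a* were higher or lower on the array labelled HDAC5. TNFSF10, RARRES1, CFB, SCNN1A and ADSS1 were lower in both comparisons, at −2.70 and −2.96 for TNFSF10 and −2.82 and −2.68 for CFB. IL1A, IL24, TRIML2, GPAT3 and the cell cycle phosphatase CDC25A were higher in both, with CDC25A 3.04-fold and 3.23-fold higher. OASL, IFITM1, IFIT2, DDX60 and the chemokine CXCL2 were lower with the mimic and higher on the array labelled HDAC5. Of these 5 genes, IFITM1 alone was counted the same way in both comparisons against the other control array, at least 2.87-fold lower with the mimic and at 0.82 on the array labelled HDAC5. There IFIT2 and DDX60 were at −0.28 and −0.37 with the mimic, CXCL2 at −0.10 with the mimic and 0.32 on the array labelled HDAC5, and OASL at −0.40 on the latter. COL1A1, SIPA1L2, SNORD13, PIGZ and MXD4 were higher with the mimic and lower on the array labelled HDAC5, with COL1A1 at 1.36 and −2.05. Against the other control array PIGZ and GPAT3 were at 0.27 and 0.38 with the mimic, and PIGZ was undetected on the array labelled HDAC5 and on the control mimic array.

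Over the 9609 genes measured in both, the differences correlated at a Pearson r of 0.323 and a Spearman correlation of 0.284 across genes, which are not independent replicates. Genes higher in both numbered 248, against 112.1 for independent lists of those sizes, and genes lower in both 421, against 168.3. Lower with the mimic and higher on the array labelled HDAC5 were 78 genes, against 121.8, and the reverse 72, against 154.9. With the control arrays exchanged between the comparisons, which again leaves them no array in common, r turned to −0.147. The counts turned with it, to 189 higher in both, 312 lower in both, 376 lower with the mimic and higher on the array labelled HDAC5, and 520 the reverse. The exchanged comparisons also counted more genes each, 1735 higher and 1689 lower for the mimic and 1673 and 2077 for HDAC5. Numbers for independent lists of those sizes are not given here, so these counts cannot be set directly beside the earlier ones. A difference between the kinds of transfection cancels when each comparison keeps its own control. After the exchange it enters both comparisons with opposite signs, which pushes r and the counts towards opposite directions. The direction found thus depended on the control each was set against, and the exchange cannot decide whether both effects share or oppose directions.

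**Figure D3:**
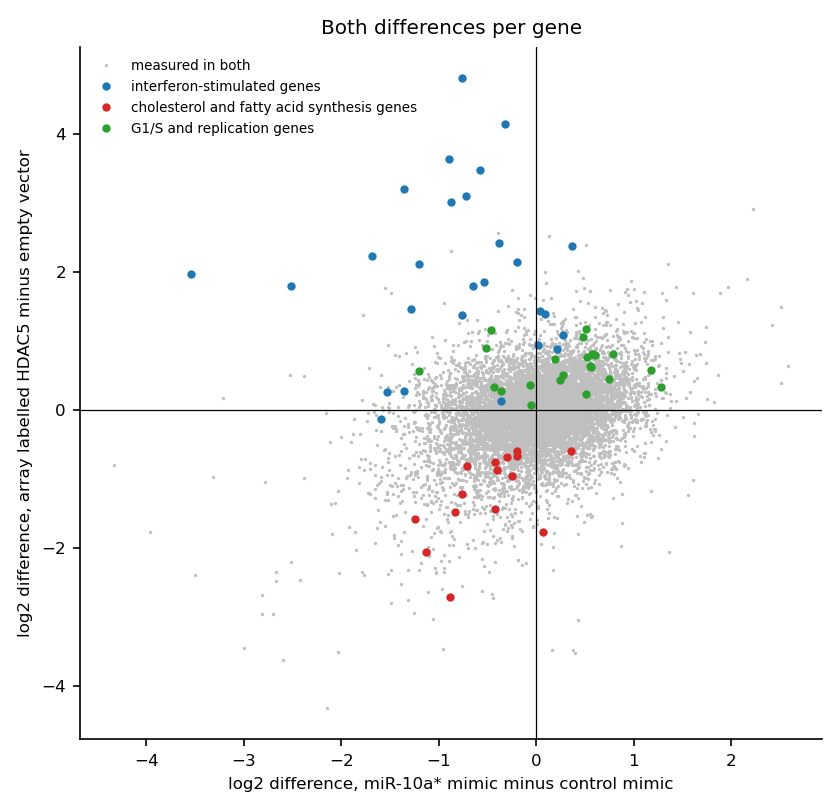
Log2 difference of the miR-10a* mimic minus the control mimic (x axis) against that of the array labelled HDAC5 minus the empty vector (y axis) for the 9609 genes measured in both (grey), with 3 gene lists coloured. Interferon-stimulated genes lie mostly at the upper left, and cholesterol and fatty acid synthesis genes below 0 on the y axis.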

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

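The tests on a low empty vector array, on a high control mimic array and on RNA from blood cells were chosen after the result each one measures was seen. Of the probes without a gene name here that were detected on at least 1 of both arrays, 1024 of 3456 (29.6%) were at least 1.5-fold apart in the mimic comparison and 797 of 3383 (23.6%) in the HDAC5 comparison. They stood out because the report uses named probes only, and the control arrays differed in 749 of 3469 (21.6%). What these probes measure was not examined, and no explanation was tested.

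Of 31 interferon-stimulated genes 27 were higher on the array labelled HDAC5, and this holds for the array as titled. Array brightness is argued against as the whole source, since the lowest median over 5 other normalizations was 1.19, and so are probes near background, since 24 members detected on both arrays had a median of 1.80. A low empty vector array stays open: the median over the control mimic array was 1.12, and IFI27, OASL and others shrink or turn with that reference. The control mimic array came from another kind of transfection. That median therefore cannot tell a low empty vector array from a plasmid response missing on it. RNA from blood cells is argued against because 0 of 14 blood and immune markers on the array were detected and at least 1.5-fold higher, with CD14 at −2.31 and CD68 at 0.04. IFNB1, the list member that encodes an interferon, was detected on the array labelled HDAC5 and not on the empty vector array, at least 1.89-fold higher. Expression of HDAC5 may raise these genes, as a hypothesis. Neither HDAC5 probe was detected, but whether the probes lie within the transfected coding sequence is not known. They therefore cannot check whether HDAC5 was expressed. A response to plasmid DNA that differed between transfections stays open, and neither this response nor an effect of HDAC5 was tested.

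Of 27 members of that list, 15 were lower on the miR-10a* array than on the control mimic array and 12 were neither higher nor lower. That difference may lie in a high control mimic array in place of a low miR-10a* array, since the median was −0.0774 when the empty vector array was the reference. The empty vector array came from another kind of transfection, so this median does not decide between them. The median over other normalizations reached −0.42, under the setting without background correction. That setting compresses differences of dim probes by construction, so it does not decide whether array brightness accounts for part of the difference. An effect of miR-10a* on interferon signalling stays open and was not tested.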

How the results depend on the processing

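The other control array and the restriction to genes detected on all 4 arrays were tests chosen after the results were seen. Of the 301 named gene values, 0 reversed under the settings fixed in advance that gave them a value, but 139 moved without background correction, 135 in the re-keyed value table, 92 at an offset of 50, 35 with the mean of detected probes and 20 under median scaling. With the other control array 186 moved, 19 reversed and 89 did neither. Of the list medians, 3 moved without background correction, 3 without a detection filter, 3 in the re-keyed value table and 1 at an offset of 50.

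A 2-fold rule gave 296 higher and 480 lower genes for the mimic and 265 and 494 for HDAC5, with 32 higher in both, 122 lower in both, 10 lower then higher and 4 higher then lower, fewer by construction. No background correction gave, in that order, 476, 507, 405, 623, 79, 157, 15 and 13. The re-keyed value table, which also lacks that correction, gave 497, 535, 423, 649, 83, 162, 16 and 13. An offset of 50 gave 824 and 843 for the mimic, 654 higher for HDAC5, and 131, 270, 31 and 22 in the combinations. These 3 settings compress differences of dim probes by construction. Detection on both arrays gave 857 lower for the mimic, 280 lower in both and 37 lower then higher, and detection on all 4 gave 280 and 37 as well, from fewer genes. Median scaling gave 976 lower for the mimic and 47 lower then higher, and the cause was not tested.

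With the other control array, HDAC5 gave 1673 higher and 2077 lower, and the combinations gave 376 lower then higher and 520 higher then lower. The correlation of both effects reversed to −0.147. Any difference between the kinds of transfection enters these exchanged comparisons with opposite signs and favours such a reversal. Reversals were taken only for medians in the outer 2.5% of their random lists on either side and for genes measured in the new pair, which leaves out, among others, p53 targets (0.13 for the mimic) and SULF1. With the other control array 20 medians moved. For the mimic, medians reversed to 0.35 for antigen presentation and 0.16 for cholesterol synthesis, and for HDAC5 to 0.185 for hypoxia. Genes that reversed for the mimic were MANCR −0.20, IFI27 2.58 (undetected on the empty vector array, so at least 3.37-fold), IFI44 0.45, H2AC6 −0.35, PMAIP1 0.29, HLA-C 0.14, ATF3 0.755, KRT19 0.71, LAMB3 −0.0398, HSPA1A 0.10 and LUM 0.0262. For HDAC5 they were OASL −0.40, TAGLN −0.47, H2BC21 0.29, H2AC6 0.36 (undetected on the control mimic array, so at least 1.19-fold), PMAIP1 −0.0018, ID3 −0.31, P4HA1 0.0183 and PGK1 0.45. Which array is out of line was not tested, and the cause was not tested.

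No paired analysis was possible because each group held 1 array, which also rules out leaving out a replicate. The seed-site comparison and its 3 alternatives were not run, as no 3' UTR sequences were used here. Signal over background was 3.02 on the miR-10a* array against 4.29 on the control mimic array, which limits dim transcripts.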

Other observations

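The tests on displaced identifiers were chosen after the result was seen. Between the control arrays, hypoxia and glycolysis genes were higher on the empty vector array than on the control mimic array, with 14 of 21 higher, 0 lower and a median of 1.01. Antigen presentation genes were lower there, with 10 of 13 lower, 0 higher and a median of −0.88. Interferon-stimulated genes had a median of −0.57, NF-kB targets −0.60 and cholesterol and fatty acid synthesis genes −0.69.

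In the copy used here of the processed value table, 10571 of 47224 identifiers (22.4%) held the values of their own signals, and later ones were displaced by 1 to 7 places. Displaced identifiers in the processed value table may account for this, since the correlation between a gene's probes was 0.238 there after the first displacement, against 0.518 for the same identifiers in the signal table, which argues against displacement in the latter. Read as identified, the processed table counted 27 of 106 named genes of the mimic comparison and 32 of 121 of the HDAC5 comparison in the reported direction. The interferon medians would be −0.10 and 0.08. VIM, an abundant filament transcript, reads 116.4 there on the empty vector array against a signal of 11123. Where the displacement arose was not tested.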
